A study of Mus musculus with 6 samples.

How the data were processed

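Total RNA from J1 mouse embryonic stem cells was measured on 6 Agilent 1-colour arrays labelled with Cy3, with 3 arrays of cells kept for 24 h with DMSO and 3 of cells kept for 24 h with 3 µM SB431542, per the labels. SB431542 is an inhibitor of the type I receptors ALK4, ALK5 and ALK7, which carry Nodal, activin and TGF-beta signals. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

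The scanner files hold intensity values per spot on a linear scale, which Agilent Feature Extraction subtracted for background and detrended within each array, per the file headers. Version 10.7 of that program is named in the submitters' processing notes. These deposited intensity values were not yet normalized between arrays. Flags for spots well above background, outlier spots and saturated spots come from the same program, per the file headers, and each flag is a score of 0 or 1. A further table holds values of the same arrays on a log2 scale deposited by the authors. Its columns had the same median of 5.18, and across probes each column correlated with the log2 processed signal of its own array at 0.99988 or above. The columns also had the same upper quartile of 8.90 and lower quartiles of 1.99, as they would after quantile normalization. How the table was normalized is not given in the sources used here, and it served only as an alternative.

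Each array held 62976 spots, of which 59305 were not controls. These belong to 55681 probes. Spots flagged as outliers were left out, which removed 81 probes, and spots of a probe were averaged. No spot was saturated (0 on every array). Between 63.9% and 66.2% of spots were well above background, and the 75th percentile of the processed signal ran from 515 to 643. For arrays, their number limits the precision.

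The log2 of the processed signal minus each array's 75th percentile over non-control probes was used. Probes well above background on at least 3 of the 6 arrays were kept, which left 36183. The scanner files gave no gene name, so each probe's accession was matched without version to a RefSeq gene table of assembly GRCm38.p6. This named 27235 probes, and 13 more carried a symbol in the file, while 28433 stayed without a symbol. The design had foreseen the files' own gene names for this step. The array grid uses mm9, so no coordinates were taken from that table. The brightest probe by mean over the 6 arrays stood for each gene, and a probe without a symbol was treated by the name in the file. This gave 25898 features, of which 15647 were genes with a symbol.

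Differences were tested with limma (lmFit and eBayes without trend, version 3.58.1 in R 4.3.3, with Python 3.11.15 for reading the files), two-sided, with Benjamini-Hochberg adjustment over all 25898 features and a threshold of 0.05. Log2 changes are SB431542 minus DMSO and errors are standard errors from this fit. "Rose" and "fell" are used of features past the threshold. A probe not well above background on any array of a group is given as "at least N-fold", which sets the mean of the brighter group against, for each dim array, the higher of the probe's own value and the lowest signal among probes well above background. Slide and scan were tested as a block. The 3 DMSO arrays and SB431542 replicates 1 and 2 lay on slide 1, and SB431542 replicate 3 lay on slide 2 with another scan. Slide and scan therefore give the same fit, which is also the fit without SB431542 replicate 3.

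The 27 gene lists were fixed before the data were examined. Their shift was tested with limma's camera at a preset correlation of 0.01, adjusted over the 27 lists, with an estimated correlation and the fry test beside it. The main lists were Nodal targets, BMP targets, core pluripotency, naive pluripotency and mesendoderm. The others covered TGF-beta and BMP pathway components, primed epiblast, primitive endoderm, trophoblast, neuroectoderm, fibroblast and 2-cell-like genes, matrix and epithelial-mesenchymal genes, LIF, FGF and WNT targets, G1/S regulators, proliferation, the stress response, p53 targets, hypoxia and glycolysis, sterol synthesis, DNA methylation and PRC2, imprinted, interferon and aryl hydrocarbon receptor genes.

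The genes named were set by a rule written before the data were examined. It took the 10 largest rises and the 10 largest falls past the threshold with a gene symbol and no overlap between the groups, 19 genes of the pathway and of pluripotency fixed by name, and up to 4 members of each list with the smallest adjusted p. Members not well above background on any array were only counted. Genes named outside this rule are said to be so. Some genes that the rule takes are not reported here, and they stay in the counts and list tests.

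On simulated data with 50 genes changed at each size among 25898 features, the steps recovered 40% at a log2 change of 0.5, 72% at 1, 90% at 2 and 90% at 3. In that simulation 9 unchanged genes were called and 0 changed genes were called in the wrong direction. It gave 200 genes a change, against 3257 features called in the data, and the Benjamini-Hochberg adjustment depends on how many change. The recovered percentages therefore need not hold for the data. Of the unchanged simulated lists, 3.2% had a camera p under 0.05. Simulated genes were drawn independently of each other, with the same SD in both groups. That share therefore does not hold for lists of correlated genes. In the data the estimated correlation within a list reached 0.199 (primitive endoderm). The alternatives tried were quantile normalization, median centring, normexp background correction with an offset of 50 (on the median signals, since the mean signal named in the design was not used here), the authors' table, other filters and probe rules, other variance models, array weights, a plain per-gene test, a replicate block, the slide block, stricter thresholds and leaving out each array.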

Results

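Transcript levels were compared between J1 mouse embryonic stem cells kept for 24 h with SB431542 (3 µM, 3 arrays) and with its solvent DMSO (3 arrays), in medium with the cytokine LIF. The J1 line is derived from the inner cell mass of a mouse of strain 129S4/SvJae. The comparison asks which transcripts respond when the Nodal, activin and TGF-beta receptors are inhibited in cells kept under self-renewal conditions. Across features, arrays correlated at 0.997 to 0.998 within DMSO, at 0.995 to 0.997 within SB431542 and at 0.991 to 0.994 between the groups. Features are not independent replicates. The leading principal component held 52.3% of the variance and separated the groups. Component 2 held 18.4%. On it SB431542 replicate 3, the only array on slide 2, lay at 30.8, against -19.5 and -19.9 for SB431542 replicates 1 and 2. The median SD over features was 0.07 on the log2 scale in DMSO and 0.12 in SB431542. Only the SB431542 arrays spanned both slides, so a slide difference may enter their larger SD. Component 3 held 12.3%. On it SB431542 replicates 1 and 2, both on slide 1, lay at -24.05 and 23.14, and the DMSO arrays between -2.69 and 6.78. The highest correlation within SB431542 (0.9965) also lay below the lowest within DMSO (0.9973). These values argue against the slide as the whole cause of the larger spread. The slide's share of it cannot be told.

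Most measured members of the Nodal target list fell. Whether they respond directly was not tested, and the inhibitor also acts on receptors of activin and TGF-beta. Of 12 measured Nodal targets, 10 fell and 0 rose (11 fell and 0 rose adjusted over the list alone). Lefty1, a Nodal antagonist and feedback target, had a log2 change of -9.43 ± 0.20 (SE, 3 arrays per group, limma adjusted p = 3.18e-05) and was well above background on 2 of 3 SB431542 arrays. Lefty2 changed by -4.85 ± 0.10 and the inhibitory Smad gene Smad7 by -4.59 ± 0.05. Smaller falls were seen for Skil (-1.34 ± 0.07), the Nodal co-receptor gene Tdgf1 (-1.04 ± 0.08) and Nodal itself (-0.63 ± 0.06). The list's median log2 change was -1.43, its camera adjusted p was 2.42e-15, and the adjusted p was 0.0252 with an estimated correlation. It was the only one of the 27 lists past the threshold with the estimated correlation. Its estimate was -0.087, below the preset 0.01, which argues against a higher correlation as the cause of its larger p. The same holds for the fibroblast (-0.034), WNT (-0.017) and p53 (0.0093) lists, which lost their calls with the estimate. The other lists that lost theirs had estimates above 0.01, so a higher correlation stays open for them. The counts of the Nodal list were 10 fell and 0 rose on slide 1 alone. The receptor genes Acvr1b (0.02 ± 0.16) and Tgfbr1 (0.04 ± 0.06) did not pass the test, and Acvr1c was not well above background on any array.

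**Figure D1:**
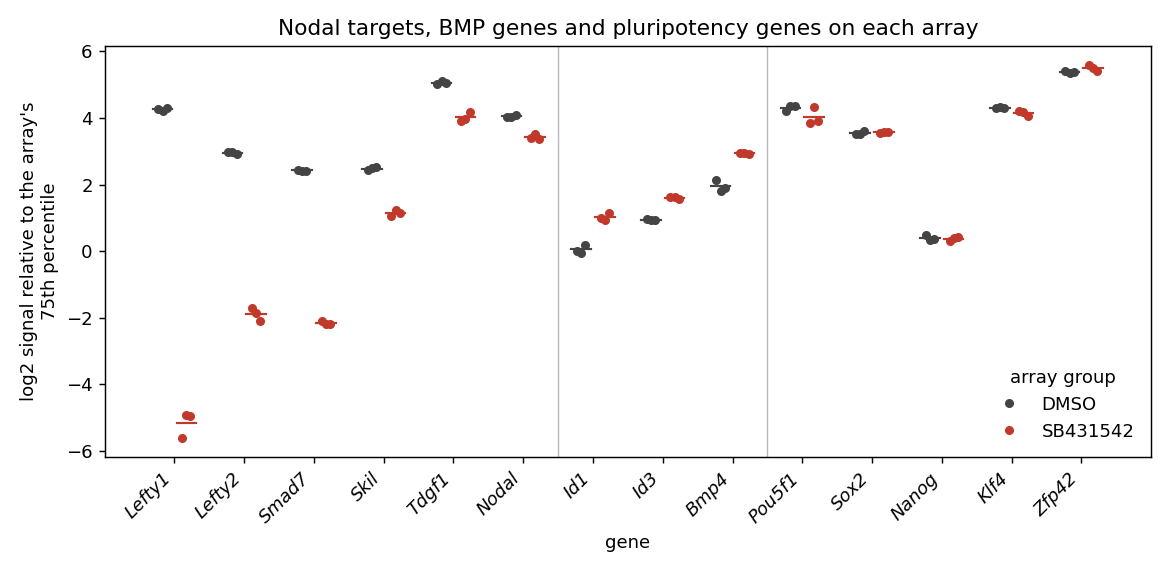
Log2 signal of single genes relative to the 75th percentile of the array (vertical axis), with a point for each of the 3 DMSO (grey) and 3 SB431542 (red) arrays and a line at each group's mean. Lefty1, Lefty2 and Smad7 lie far lower on the SB431542 arrays, Id1, Id3 and Bmp4 lie higher, and Sox2 (0.03) and Nanog (-0.02) differ little on the log2 scale. Lefty1 was well above background on 2 of 3 SB431542 arrays.

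Of 25898 features tested, 3257 changed, 1344 higher and 1913 lower. At least 2-fold changes were seen in 405, of which 92 were higher and 313 lower. The groups did not overlap for 36.0% of features, against 10% by chance. The count of changed features was 1619, 1467 and 1557 without DMSO replicate 1, 2 and 3, while the higher features numbered 848 and 762 without SB431542 replicate 1 and 2. Those lower numbered 1020, 972 and 925 without DMSO replicates 1, 3 and 2, and the higher 599, 542 and 585 without DMSO replicates 1, 2 and 3. On slide 1 alone, which is the fit with slide as a block, 2911 features changed.

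Among the largest falls outside the Nodal list were the homeobox gene Hoxb13 (-4.58 ± 0.06), Mup6 (-3.90 ± 0.13), Fgf15 (-3.67 ± 0.36, well above background on 1 of 3 SB431542 arrays) and Tmem63a (-3.48 ± 0.08). Fgf5, a growth factor gene of the primed epiblast, was at least 2.51-fold lower and Duxbl1 at least 8.05-fold lower, with neither well above background on any SB431542 array. Mup6 and Duxbl1 belong to families of near-identical copies whose probes may share signal, so their identity is uncertain. The largest rises were smaller. Spic rose by 2.17 ± 0.07 on the log2 scale, Asb9 by 2.04 ± 0.08, the axon guidance gene Ntn1 by 2.02 ± 0.09 and Ackr4 by 1.86 ± 0.07. Several others were not well above background on any DMSO array, so that Ephb1 was at least 2.39-fold higher, Slc6a14 at least 2.11-fold, Plxna4 at least 1.69-fold and Kcnh8 at least 1.501-fold. The ranking used fitted values, also for dim probes. Tgfbi, measured on all arrays, rose 2.89-fold, above these bounds, so their place among the largest rises is not shown. The same holds for Fgf5 among the falls, since Atf3, measured on all arrays, fell 3.995-fold. The probes of Tmem255a disagreed. The brightest was not well above background on any DMSO array and was at least 8.17-fold higher, while the other, well above background on 2 DMSO arrays, changed by 0.39. Ly6a rose by 2.06 ± 0.38. Its limma adjusted p was 0.0842 and 0.0510 without DMSO replicates 2 and 3, and 0.0662 and 0.0622 without SB431542 replicates 2 and 3. That of Slc6a14 was 0.05002 and 0.0509 without SB431542 replicates 2 and 3.

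BMP targets moved in both directions. Of 10 measured, 2 rose and 4 fell (3 and 4 adjusted over the list alone), and on slide 1 alone 2 rose and 3 fell. Id1 (0.97 ± 0.09) and Id3 (0.66 ± 0.05), inhibitors of basic helix-loop-helix factors, rose, while Smad7, also a Nodal target, Hey1 (-1.27 ± 0.09) and Smad6 (-0.62 ± 0.05) fell. Id2 (0.11 ± 0.08) did not pass. The list's median was 0.03 and its mean -0.48, so these differ in sign, and camera gave an adjusted p of 0.489. Among 13 BMP pathway components 1 rose and 1 fell (1 and 1 adjusted over the list alone), the ligand gene Bmp4 by 0.98 ± 0.09 and Bmp8b by -0.54 ± 0.09, with a median of -0.02, a mean of 0.05 and a camera adjusted p of 0.997. The adjusted p of Bmp8b was 0.0570, 0.0544 and 0.0587 without DMSO replicates 1, 2 and 3. Of 20 TGF-beta pathway components, 2 rose and 5 fell (3 and 5 adjusted over the list alone), and on slide 1 alone 1 rose and 5 fell. With all arrays, Cfc1 (1.00 ± 0.13) was higher and Inha (-0.87 ± 0.12) and Tgfb2 (-0.64 ± 0.08) were lower. The median was 0.04, the mean -0.05 and the camera adjusted p 0.725. The brightest Gdf1 probe fell by 0.50 while another changed by 0.26.

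None of the 5 pluripotency genes fixed by name passed the test. Pou5f1 (-0.29 ± 0.14, limma adjusted p = 0.244), Sox2 (0.03 ± 0.05), Nanog (-0.02 ± 0.06), Klf4 (-0.16 ± 0.06) and Zfp42 (0.12 ± 0.06) all missed the threshold. Of 11 core pluripotency genes, 4 fell and 0 rose (4 and 1 adjusted over the list alone). Among those that fell were Tdgf1, which is also in the Nodal list, Utf1 (-0.42 ± 0.06) and L1td1 (-0.42 ± 0.06). The camera adjusted p was 0.0263, and the adjusted p was 0.195 with an estimated correlation and 0.0578 without SB431542 replicate 3, the fit on slide 1 alone. Of 20 naive pluripotency genes, 5 rose and 6 fell (5 and 8 adjusted over the list alone). Fbxo15 (0.77 ± 0.06) and Dppa3 (0.77 ± 0.07) rose, while Tcl1 (-0.87 ± 0.09) and the T-box gene Tbx3 (-0.68 ± 0.05) fell. The camera adjusted p was 0.126, and it passed the threshold under normexp (0.0380) and with no filter on dim probes (0.0426). Of 12 primed epiblast genes, 5 fell and 0 rose (7 and 0 adjusted over the list alone), among them Fgf5, Fgf15, the POU factor gene Pou3f1 (-0.98 ± 0.08) and Foxd3 (-0.59 ± 0.07). The camera adjusted p was 4.2e-05, and the adjusted p was 0.195 with an estimated correlation.

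Mesendoderm, trophoblast and primitive endoderm markers included genes that rose and genes that fell, while neuroectoderm, fibroblast and 2-cell-like genes included falls and 0 rises. Of 12 measured mesendoderm genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone), with Fgf8 changing by -1.58 ± 0.07. Cxcr4 fell by 0.96 on the log2 scale and Hhex rose by 0.37. The adjusted p of Cxcr4 was 0.0692, 0.0654 and 0.0750 without DMSO replicates 1, 2 and 3 and 0.0504 without SB431542 replicate 2, and that of Hhex was 0.0891 and 0.0728 without DMSO replicates 2 and 3 and 0.0650 and 0.05997 without SB431542 replicates 1 and 2. The list's median was 0.02, its mean -0.10 and its camera adjusted p 0.859. The brachyury gene T was well above background on 2 arrays and was not tested. Of 11 trophoblast genes, 5 rose and 1 fell (5 and 3 adjusted over the list alone), with Tfap2c (1.22 ± 0.05), Gata3 (0.97 ± 0.11) and Tfap2a (0.64 ± 0.08) higher, Krt8 (-0.49 ± 0.06) lower and a camera adjusted p of 0.219. Of 15 primitive endoderm genes, 1 rose and 3 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.257). Of 11 neuroectoderm genes, 0 rose and 3 fell (0 and 3 adjusted over the list alone), with Nes at -0.60 ± 0.06. Their median was 0.08, their mean -0.06 and their camera adjusted p 0.527. Of 12 fibroblast genes, 0 rose and 5 fell (1 and 6 adjusted over the list alone), with the collagen gene Col1a2 at -1.05 ± 0.12. Their camera adjusted p was 0.0216, and the adjusted p was 0.195 with an estimated correlation. Of 7 measured 2-cell-like genes, 4 fell and 0 rose (4 and 0 adjusted over the list alone), namely Tcstv3 (-1.30 ± 0.09), Tcstv1 (-1.15 ± 0.13), Zscan4f (-1.02 ± 0.07) and Zscan4c (-0.87 ± 0.07), which belong to families of near-identical copies. The camera adjusted p was 0.00447, and the adjusted p was 0.195 with an estimated correlation.

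**Figure D2:**
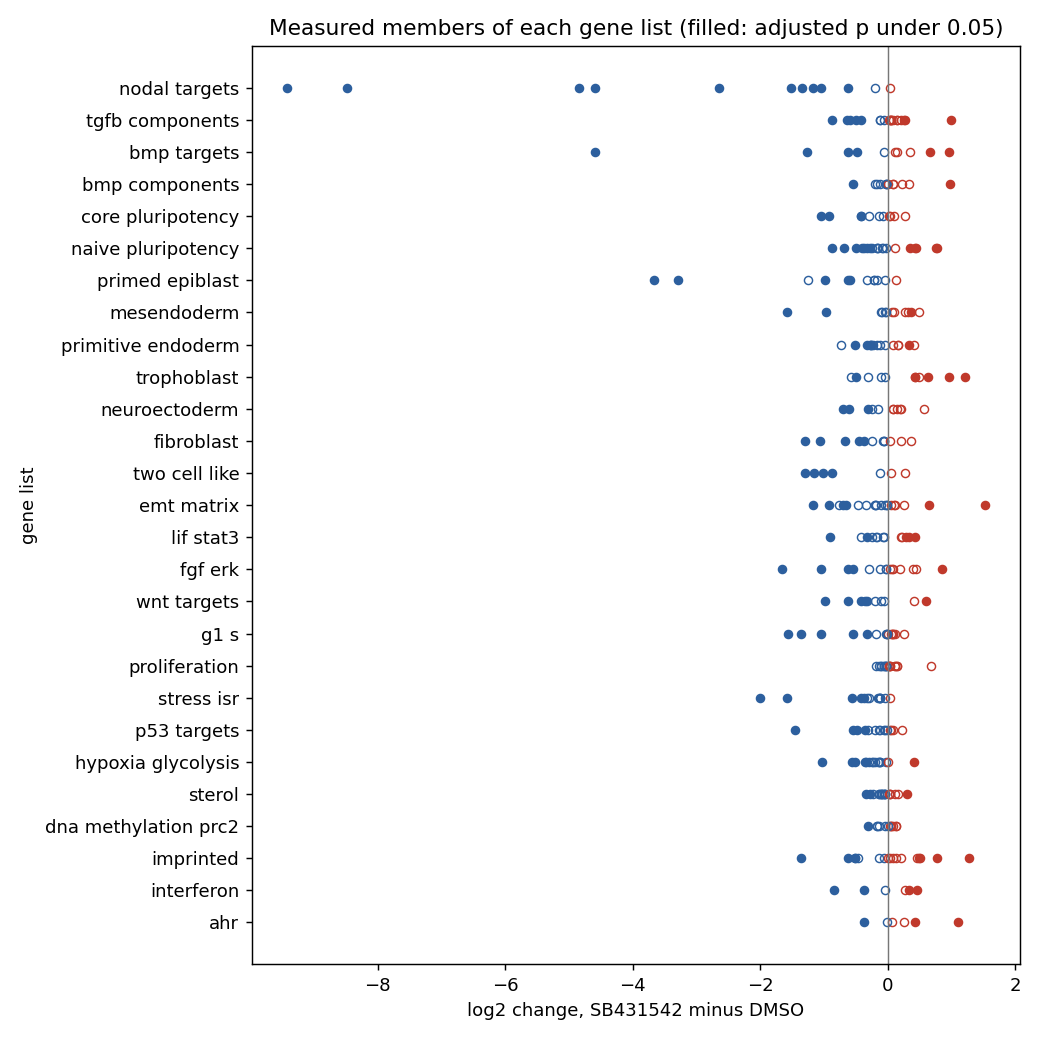
Log2 change, SB431542 minus DMSO (horizontal axis), of every measured member of the 27 gene lists (vertical axis), with a point per gene, red above 0 and blue below, filled where the limma adjusted p passed the threshold of 0.05. Nodal targets reach -9.43, and proliferation genes lie between -0.17 and 0.69 with no filled point. Points of probes dim in a group are fitted values, not bounds.

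Some FGF and ERK targets and some G1/S regulators fell, while neither list's shift passed camera in the main setting. Of 15 FGF and ERK targets, 1 rose and 4 fell (1 and 4 adjusted over the list alone). The immediate early genes Egr1 (-1.66 ± 0.08) and Fos (-0.63 ± 0.05) and the growth regulator Myc (-1.04 ± 0.07) fell and the phosphatase gene Dusp4 (0.85 ± 0.09) rose, with a camera adjusted p of 0.257. Of 16 G1/S regulators, 0 rose and 5 fell (0 and 5 adjusted over the list alone), with the cyclin gene Ccnd2 at -1.56 ± 0.08 and the cyclin-dependent kinase inhibitor gene Cdkn1c at -1.36 ± 0.08. Their camera adjusted p was 0.109, and it passed the threshold under normexp background correction (0.00431) and with no filter on dim probes (0.0426). None of 18 proliferation genes passed limma's test (0, and 0 adjusted over the list alone), with 2 at an unadjusted p under 0.05. Their median was 6.37e-05, their mean 0.04 and their camera adjusted p 0.859 with a downward sign. Of 10 WNT targets, 1 rose and 5 fell (2 and 6 adjusted over the list alone), and on slide 1 alone 2 rose and 4 fell. With all arrays, Cdx1 changed by -0.99 ± 0.05. The list's camera adjusted p was 0.0186. It was 0.195 with an estimated correlation and 0.0989 with the mean of a gene's probes. Of 13 LIF and STAT3 targets, 3 rose and 2 fell (5 and 2 adjusted over the list alone), with the kinase gene Pim1 at -0.91 ± 0.09 and a camera adjusted p of 0.859.

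Members of the stress response, p53 and hypoxia lists fell. Of 14 genes of the integrated stress response, 5 fell and 0 rose (8 and 0 adjusted over the list alone), with the transcription factor gene Atf3 at -1.998 ± 0.15, Chac1 at -1.58 ± 0.11 and Herpud1 at -0.56 ± 0.07. Their camera adjusted p was 2.17e-05, and the adjusted p was 0.195 with an estimated correlation. Of 15 p53 targets, 4 fell and 0 rose (5 and 1 adjusted over the list alone), with Gdf15 at -1.45 ± 0.09. Their camera adjusted p was 0.0337, and the adjusted p was 0.195 with an estimated correlation, 0.0527 with the mean of a gene's probes, 0.0698 without SB431542 replicate 1 and 0.0788 without SB431542 replicate 2. Of 16 hypoxia and glycolysis genes, 1 rose and 5 fell (1 and 8 adjusted over the list alone), with the carbonic anhydrase gene Car9 at -1.03 ± 0.08 and Pdk1 at 0.41 ± 0.06. Their camera adjusted p was 0.000305, and the adjusted p was 0.195 with an estimated correlation. Of 19 sterol and lipid genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.257).

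Among 20 matrix and epithelial-mesenchymal genes, 2 rose and 4 fell (3 and 6 adjusted over the list alone). The matrix gene Tgfbi rose by 1.53 ± 0.05, while the matricellular gene Ccn2 (-0.92 ± 0.08) and the actin gene Acta2 (-0.66 ± 0.05) fell. The camera adjusted p was 0.121, and 0.0426 with no filter on dim probes. Of 17 imprinted genes, 3 rose and 4 fell (5 and 4 adjusted over the list alone). The non-coding RNA gene H19 rose by 1.28 ± 0.08, while Cdkn1c and Dlk1 (-0.62 ± 0.06) fell. The list's median was 0.04 and its mean 0.02, camera gave an adjusted p of 0.859 with an upward sign, and fry's sign was downward. Of 6 aryl hydrocarbon receptor genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone), with the cytochrome P450 gene Cyp1a1 at 1.11 ± 0.08 and Nqo1 at 0.43 ± 0.05 (camera adjusted p = 0.257). Of 6 interferon genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone), with Ddx58 at 0.46 ± 0.06. Their median was 0.12, their mean -0.03 and their camera adjusted p 0.725. On slide 1 alone 2 of them rose and 0 fell. Of 12 DNA methylation and PRC2 genes, 1 fell and 0 rose (0 and 0 adjusted over the list alone), Dnmt3l at -0.30 ± 0.07. Its adjusted p was 0.132, 0.153 and 0.154 without DMSO replicates 1, 2 and 3 and 0.112 and 0.127 without SB431542 replicates 1 and 2. That list's median was 0.02, its mean -0.02 and its camera adjusted p 0.859.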

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

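The alternatives were planned before the data were examined, except the counts of list members without SB431542 replicate 3, which were chosen after seeing the data and stayed within 1.5 times for the main lists. The count of changed features ran from 1222 to 4240 over all settings, against 3257. It was 2097 (791 higher) with no filter on dim probes, which tests more features, and 1222 (431 higher, 791 lower) at an adjusted p under 0.01. Leaving out single arrays gave 1467 to 2911 changed features, 542 to 1235 higher and 925 to 1676 lower, and leaves fewer samples. At least 2-fold changes numbered 109 (28 higher, 81 lower) under normexp, which changed the signal, the background method and the offset together, 238 (55 higher, 183 lower) under treat against 1.5-fold, and the higher ones 145 with every probe on its own. The Nodal target shift passed the threshold under each setting in which list shifts were computed, which leaves out every probe on its own, the plain per-gene test and the stricter thresholds. The BMP list's adjusted p was 5.57e-05 under fry, which does not compare with other genes. That of core pluripotency was 0.0578 with slide or scan as a block, 0.195 with an estimated correlation, and 0.0196 to 0.0578 when leaving out an array. That of naive pluripotency was 0.0380 under normexp, 0.0426 with no filter and 0.0158 under fry. Among the other lists, G1/S regulators gained a call under normexp (0.00431) and with no filter (0.0426), and matrix genes with no filter (0.0426), while WNT and p53 targets lost theirs with the mean of a gene's probes (0.0989 and 0.0527). Under fry, the trophoblast, neuroectoderm, matrix, FGF, G1/S, sterol, interferon and aryl hydrocarbon receptor lists also passed, at 0.000375 to 0.0158. Correlation aside, the cause was not tested for the changes in list calls. Of the 129 named genes 0 reversed in the settings run for single genes. With the filter on all 6 arrays 117 of them could be compared. Under the trend and robust variance, the plain per-gene test and the replicate block the estimates could not differ from the main fit. With every probe on its own the same probe was read for them, so no reversal was possible there either. Of all 3257 called features, 42 had the opposite sign with every probe on its own, where the probe read could be another. The number was 7 with the mean of a gene's probes and 3 under normexp. Of the 108 named genes called, 32 lost their call in at least 1 fit without an array.

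With the replicate block, 1567 features changed, 545 higher and 1022 lower. The residuals of same-numbered arrays correlated at 0.00, 0.07 and -0.06 for replicates 1, 2 and 3. DMSO replicate 2 correlated best with its own number (at most 0.006 with another). DMSO replicates 1 and 3 correlated better with another number (up to 0.05 and 0.07). With so few pairs, and SB431542 replicate 3 on another slide, these values cannot show whether same-numbered arrays were paired. Signal over background limits the dim probes, which have only a bound.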

Other observations

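The tests of patterns in this part were chosen after the results were seen, and so were the Hox, GTPase and interferon-related genes and the unnamed features named here. Genes of the HoxB cluster, which pattern the body axis, were lower with SB431542. Of 9 measured Hoxb genes 7 fell and 0 rose, with Hoxb13 at -4.58, Hoxb4 at -1.75 ± 0.17, Hoxb7 at -1.46 ± 0.15 and Hoxb2 at -1.25 ± 0.07. Of 12 measured genes of the other Hox clusters 4 fell and 0 rose. By Fisher's exact test, two-sided, this difference in calls did not pass (p = 0.0805). Without SB431542 replicate 3, on slide 1 alone, 8 Hoxb genes fell and 0 rose, while 3 of the others fell and 1, Hoxc4 (0.61, adjusted p = 0.0264), rose (exact p = 0.00752 for the falls). The cluster was picked after its fall was seen and its genes are not independent, so neither p tests the pattern on fresh data. Calls of Hoxb5 were lost without any 1 DMSO replicate (adjusted p of 0.0560, 0.0516 and 0.0520 without DMSO replicates 1, 2 and 3), and those of Hoxb6 without DMSO replicates 1, 2 and 3 (0.107, 0.137 and 0.109) and without SB431542 replicates 2 and 3 (0.111 and 0.0791).

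Some genes of guanylate-binding and immunity-related GTPases, which act in cell-autonomous defence, fell, as did Rtp4. Gbp2 changed by -3.06 ± 0.26, Irgm1 by -3.28 ± 0.12 and Gbp3 by -2.46 ± 0.20 (well above background on 1 of 3 SB431542 arrays), and Gbp2b and Rtp4 were at least 5.58-fold and 4.79-fold lower. Of the 10 other measured members of these GTPase families 1 fell, Tgtp2 (-1.11 ± 0.09), and 1 rose, Gbp10 (0.32 ± 0.08), with a median log2 change of 0.23. The adjusted p of Gbp10 was 0.152, 0.135 and 0.113 without DMSO replicates 1, 2 and 3, and 0.111 and 0.0761 without SB431542 replicates 2 and 3. Oasl2 (-2.46 ± 0.16), Irf1 (-0.70 ± 0.05) and the receptor gene Ifngr1 (-0.67 ± 0.05) fell, while Gbp4 (-0.06), Gbp9 (0.03), Igtp (-0.12), Irgm2 (0.35) and Gbp6 (0.58) did not pass. Of features without a symbol, 2 on chromosome 18 of mm9 fell by 5.68 (75518299 to 75524782) and 4.69 (75513062 to 75523889) on the log2 scale. Their intervals overlap and carry the same strand letter, so they may read the same region. A feature on chromosome 16 (9129538 to 9137898) rose by 1.75, and another on chromosome 5 (52186651 to 52187148) was at least 3.28-fold higher.

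The 6 arrays make only 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 3257 features, and 405 changed at least 2-fold, against a highest of 0 and 0 in the other splits, so 1 split of 10 was as large for each. The tables argue against the slide as the whole cause, since 94.8% of the 405 features (384) were called the same way by the 5 arrays of slide 1, which hold both groups. These arrays are also in the fit of all 6. The row on the slide was tested with separate arrays. Of 311 features called at least 2-fold from replicates 1 and 2 of both groups, SB431542 replicate 3, which lay in row 1 with the DMSO arrays, differed from DMSO replicate 3 in the same direction for 97.4%. A response to the inhibitor stays the open biological explanation, as a hypothesis.

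For the fall of the Hoxb genes, shared signal between paralogs would lower the paralogs in other clusters as much. Among the 4 Hoxb genes that fell and whose probe and tested paralogs were well above background on all arrays, the median log2 difference from the lowest paralog was -1.35 (quartiles -1.92 and -0.96), and the gap was over 2 standard errors in Hoxb4, Hoxb7 and Hoxb13. The Hoxb genes were taken because they fell and the paralogs were not, which favours a negative difference. Hoxb3 and Hoxb9, which did not pass with all arrays, were not compared. Shared signal stays open for Hoxb6 (-0.25 ± 0.22) and for the 3 others that fell, Hoxb1, Hoxb2 and Hoxb5, whose own probe or paralogs were dim on some arrays. The slide is argued against as the whole cause too, since 85.7% of the 7 Hoxb genes that fell (6) were also called on slide 1 alone. A response to the inhibitor stays open, as untested.

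For Gbp2, Gbp2b, Gbp3, Irgm1 and Rtp4, a weaker interferon response as a whole could lower the interferon list too. Of its 12 members 6 were measured, of which 2 rose and 2 fell. Their median was 0.12 and the lowest -0.84, above the smallest of the 5 falls with dim genes at their bound (-2.26, Rtp4). This cannot decide, because the 5 genes were picked for their falls and the other list members were too dim to test. A weaker interferon response, whole or in part, stays open, since Oasl2, Irf1 and Ifngr1 fell too. Whether the 3 Gbp probes share signal between near-identical copies cannot be told apart, because probe sequences were not analysed here. A response to the inhibitor stays open too, as untested.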
